A study of Homo sapiens with 8 samples.

How the data were processed

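Gene expression was measured by RNA sequencing in 8 libraries of human T cells, 4 per group. Per the labels, the cells were isolated as naive CD4+ CD45RO- T cells and were differentiating into Th17 cells, the helper T cells named for interleukin 17. Control cultures received decidual cell medium that had not been conditioned, and the others received medium conditioned by decidual cells, the cells of the uterine lining in pregnancy. Total RNA was extracted with a column kit made for small samples, and libraries followed a standard Illumina protocol, per the labels' protocols. Whether the kit marks strand, and whether the counting used strand, is not given in the sources used here.

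The deposited values are raw counts per gene, whole numbers that the authors did not normalize. The submitters' processing notes name CASAVA, TopHat2 version 2.1.1, HTSeq and the human genome build GRCh37, with no settings, and the annotation release is not given in the sources used here. Each of the 8 files held 57905 Ensembl gene IDs and 0 entries that name no gene, so the share of reads outside genes is unknown. Groups and replicate numbers were taken from the sample titles. The files' own names carry a prefix that differs between the groups and numbers that differ from the replicate numbers, which no label explains. If the prefix marks a time or a preparation, that difference and the medium cannot be told apart. The labels do not say whether the 4 libraries of a group came from separate donors, cultures or days, so p-values measure only the spread between these libraries, which may be technical.

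The reference supplied was GRCh38 and not the build of the counts. It was used for gene names, gene types, transcript length and GC content, and no coordinates were taken from it. Of the 57905 IDs, 51996 matched a gene name and 5909 did not. Genes on the Y chromosome, XIST and TSIX, 515 in all, were left out before any test because the cells came from human donors. Genes with a near-identical copy, such as ribosomal protein genes and their pseudogenes, the interferon lambda genes, the metallothioneins and HSPA1A with HSPA1B, have uncertain counts, since reads can be split or lost between copies.

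Conditioned libraries were compared with control libraries in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood F test, TMM scaling (trimmed mean of M values) and the default filter on low counts (filterByExpr, minimum count 10). P-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05, and all tests were two-sided. The filter left 13773 genes, which held 99.9% of the counts. Log2 fold changes are conditioned over control, with a standard error (SE) derived from the F statistic. Levels are CPM (counts scaled to a common library size) after TMM scaling, as mean ± SD over the 4 libraries of a group. The labels number the libraries 1 to 4 in both groups, and the fit did not use those numbers.

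A total of 46 gene lists were fixed before the data were examined. They cover T helper programmes, signalling pathways, metabolism, markers of other cell types and signs of RNA quality. The 43 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list's genes with all other genes, and adjusted over the 43. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were the alternatives. List members under older names were looked up through a table of synonyms. CCL3, CCL4, CCL5, TXNIP, UHRF1, ACACA and a few others matched no ID and were not analysed here.

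The genes named in the text follow a rule set before the data were examined. It names 14 T cell genes in every case. It adds the 12 largest rises and 12 largest falls among changed genes with a mean of at least 2 CPM, a gene symbol and groups that did not overlap. It also adds up to 4 changed members with the smallest p from each list that was called or had at least 3 changed members, which made 179 genes. Genes whose presence is a property of a donor were never named. Genes outside this rule are said to be chosen after their values were seen.

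The alternatives fixed in advance were DESeq2 size factors, upper-quartile factors and no composition factor, no filter and a stricter filter (over 1 CPM in at least 4 libraries), DESeq2 1.42.0, limma-voom with and without library weights, the replicate number as a block, and each of the 8 libraries left out in turn. A correction for transcript length and GC content, the removal of the 2 most abundant unnamed gene IDs, and the removal of 3 libraries rich in those IDs were chosen after seeing the data. The pipeline was tested on simulated counts for conditioned against control over 13689 genes with 200 changed. It recovered 14.0% of genes changed 1.25-fold, 66.0% at 1.5-fold, 90.0% at 2-fold and 100% at 3-fold (50 genes each), and 11 of its 146 calls were false. A planted lower list was found, and 1 of 40 random lists was called. In the data 49.8% of genes were called, far more than were changed in the simulation, so these rates do not carry over. The simulation did not test the scaling when so many genes change.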

Results

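The series holds 8 RNA-seq libraries of human CD4+ T cells that were differentiating towards Th17 cells, 4 given medium conditioned by decidual cells and 4 given the medium unconditioned. The comparison asks which genes change in differentiating Th17 cells under the conditioned medium. Control libraries 1 to 4 held 23673015, 32506815, 15952803 and 30160914 counts, and conditioned libraries 1 to 4 held 32060077, 21039760, 20596477 and 21687821. Mean totals did not differ beyond the spread (exact two-sided permutation test over 70 splits, p = 0.714). Mitochondrially encoded genes took 4.59% ± 0.697 of counts in control and 2.88% ± 0.753 in conditioned libraries (SD, n = 4), with p = 0.0286 in the exact permutation test, the smallest it can give, and 0.171 adjusted over 6 library measures. A pair of unnamed gene IDs took between 7.31% and 21.0% of counts, with over 15% in control libraries 1 and 3 and conditioned library 4. The first principal component separated the groups and held 66.6% of the variance. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 10.2 or more).

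In T cells given conditioned medium, interferon-stimulated genes were higher and ribosomal protein mRNAs were lower. MX1, an antiviral GTPase, rose from 16.6 ± 3.84 to 91.1 ± 14.97 CPM (SD, n = 4), and 30 of 35 listed type I interferon response genes rose. All 32 listed ribosomal protein mRNAs fell, by a median log2 fold change of -1.15. Genes of the Th17 programme moved both ways, with IL21 and IL23R higher and CCL20 lower. Mitotic, respiratory chain and unfolded protein response genes were mostly lower.

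Of 13773 genes tested, 6863 (49.8%) changed, 3451 higher and 3412 lower (edgeR adjusted p under 0.05). At least 2-fold changes were made by 520 of the higher and 397 of the lower genes. The 4 conditioned libraries lay wholly above or below the 4 control libraries for 6171 genes (44.8%), where chance gives 2.86%. Without a composition factor the median of all genes moved to 0.34 and the calls to 6549 higher and 1028 lower, so that 86.4% of calls were higher, against 50.3% with TMM; directions below are relative to the TMM scale. Counts of list members below are over all genes tested; adjusted over the list alone they were the same except for 28 lower respiratory chain, 11 lower glycolysis, 11 lower cyclic AMP, 2 lower retinoic acid, 10 higher chemokine receptor, 8 higher p53 and 4 higher cholesterol genes, 3 higher STAT3 targets, and 1 higher and 3 lower NF-kB targets. Without control libraries 1 and 3 and conditioned library 4, which were rich in the unnamed IDs, 4140 genes changed, 2086 higher and 2054 lower.

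Th17 genes were split. IL21, a cytokine of Th17 and follicular helper T cells, rose from 16.6 ± 1.41 to 33.5 ± 5.86 CPM, a log2 fold change of 1.01 ± 0.12 (SE, n = 4 per group, edgeR adjusted p = 9.56e-06). IL23R, the receptor chain for interleukin 23, rose from 29.7 ± 0.840 to 51.1 ± 8.71 CPM (log2 0.78 ± 0.11, edgeR adjusted p = 3.64e-05). CCL20, the chemokine ligand of CCR6, fell from 5.79 ± 0.802 to 2.98 ± 0.358 CPM (log2 -0.96 ± 0.15, edgeR adjusted p = 0.000114). The transcription factors AHR (log2 1.20 ± 0.13), MAF (0.89 ± 0.09) and IRF4 (0.68 ± 0.09) rose. RORC, which encodes the Th17 master regulator RORγt, had 1.68 ± 0.596 CPM in control and 2.09 ± 0.167 in conditioned libraries and did not pass the test (edgeR adjusted p = 0.316), except without a composition factor (0.0293). Of 22 measured members of the Th17 programme 7 rose, 5 fell and 10 did not pass, and the list as a whole was not called (camera adjusted p = 0.285).

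IL17A and IL22 had few counts, and IL17F had more. IL17F had 6.08 ± 2.01 CPM in control and 4.11 ± 1.62 in conditioned libraries (log2 -0.58 ± 0.25, edgeR adjusted p = 0.0654). It passed the threshold without control library 2 (log2 -0.74, edgeR adjusted p = 0.0349) and without conditioned library 2 (-0.89, 0.00276). With no filter on low counts it passed too (-0.60, 0.000795). Conditioned library 2 had 6.48 CPM, against 2.90 to 3.69 in the other conditioned libraries. IL17A had 4 to 26 counts per control library and 0 to 7 per conditioned library, and IL22 had 9 to 45 and 7 to 11. CCR6, the chemokine receptor typical of Th17 cells, had 1 to 3 and 4 to 12 counts, and IL10, an anti-inflammatory cytokine, had 0 to 5 and 5 to 15. These 4 genes were below the filter. An edgeR fit with no filter gave log2 fold changes of -1.72 ± 0.57 for IL17A (adjusted p = 0.0131) and -1.32 ± 0.38 for IL22 (0.00368). It gave 1.86 ± 0.68 for CCR6 (0.0294) and 1.42 ± 0.61 for IL10 (0.0779). In that fit SEs shrank for genes with a wide spread, such as IL17F (0.25 to 0.16) and MT-ND4 (0.21 to 0.10). Its p-values therefore understate the spread between libraries. IL17A had 0.91 CPM in control library 4, at most 0.33 in the other control libraries and up to 0.29 in conditioned libraries. The IL22 groups overlapped, with 0.32 CPM in control library 4 and 0.51 in conditioned library 4.

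**Figure D1:**
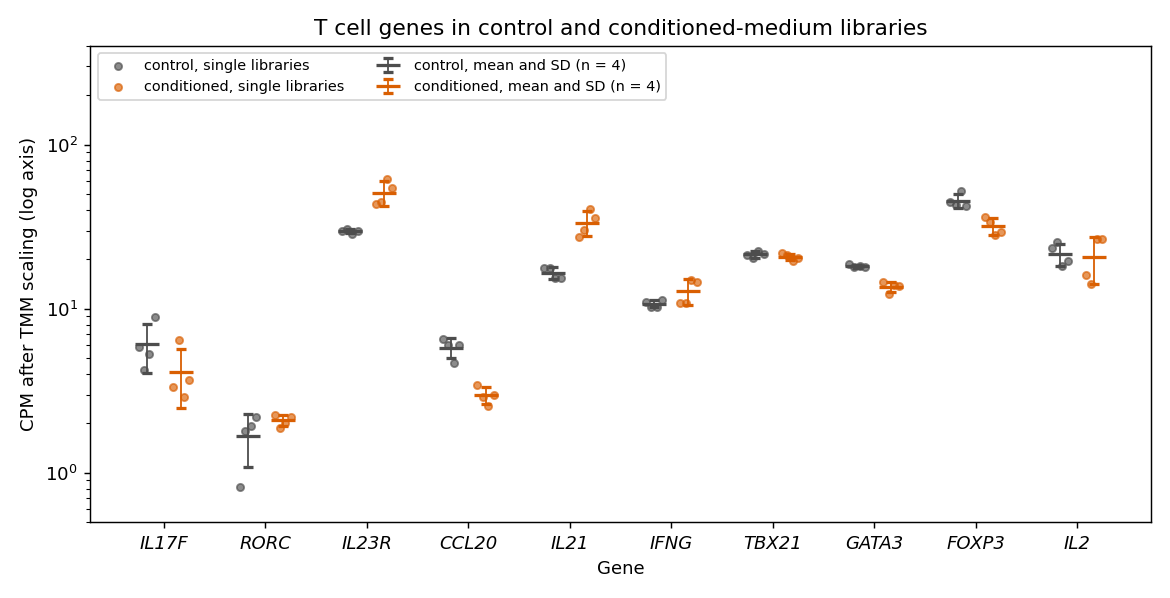
Level of the 10 always-named T cell genes that passed the filter, in CPM after TMM scaling on a log axis; points are single libraries, and bars are the mean ± SD of 4 control (grey) or 4 conditioned (orange) libraries. IL23R and IL21 lie higher in every conditioned library than in any control library, while CCL20, GATA3 and FOXP3 lie lower.

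Markers of other helper lineages also moved in both directions. GATA3, the Th2 master regulator, fell from 18.2 ± 0.399 to 13.6 ± 0.899 CPM (log2 -0.41 ± 0.09, edgeR adjusted p = 0.0015). FOXP3, the regulatory T cell master regulator, fell from 45.5 ± 4.402 to 32.0 ± 3.78 CPM (log2 -0.50 ± 0.10, edgeR adjusted p = 0.00073). TBX21, which encodes the Th1 regulator T-bet, had a log2 fold change of -0.04 ± 0.09, IFNG of 0.25 ± 0.13 and IL2 of -0.07 ± 0.18, and none of these passed (edgeR adjusted p = 0.686, 0.116 and 0.774). IFNG passed without conditioned library 1 (0.0489) or 2 (0.0482), without a composition factor (0.000615) and after the length and GC correction (0.000336). For IL2 and IFNG the conditioned libraries divided into pairs. IL2 had 16.02 and 14.11 CPM in libraries 1 and 2, below the control range of 18.3 to 25.4. Libraries 3 and 4 had 26.51 and 26.60 CPM, above that range. The mean IL2 change therefore hides opposite shifts. IFNG had 10.84 and 10.78 CPM in conditioned libraries 1 and 2, within the control range of 10.3 to 11.3. It had 15.01 and 14.54 CPM in 3 and 4, above that range. Without a composition factor GATA3 (log2 -0.09, edgeR adjusted p = 0.612) and FOXP3 (-0.17, 0.26) did not pass. Without the 3 libraries rich in unnamed IDs GATA3 (-0.39, 0.0544) and FOXP3 (-0.37, 0.0594) did not pass, with fewer libraries tested.

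In the Th1 and cytotoxic list of 16 measured genes 7 rose and 4 fell. IL12RB2, an interleukin 12 receptor chain, rose (log2 0.92 ± 0.08), as did the transcription factor HLX (1.08 ± 0.14), and the chemokine receptor CXCR3 fell (-1.17 ± 0.11). In the Th2 list 3 of 6 rose and 2 fell, with CCR4 (log2 1.15 ± 0.08) and the cytokine IL9 (1.70 ± 0.23) higher and NFIL3 (-0.74 ± 0.07) lower. In the regulatory T cell list 8 of 18 rose and 5 fell, with NT5E, which encodes the ectonucleotidase CD73 (1.48 ± 0.11), PRDM1 (0.92 ± 0.10) and IL2RA (0.64 ± 0.08) higher. None of these 3 lists was called (camera adjusted p = 0.232, 0.308 and 0.124), but the Th1 list (0.0222) and the regulatory list (0.0315) passed after the length and GC correction, and the regulatory list with no filter (0.029). The follicular helper list was called as higher (camera adjusted p = 0.029; adjusted p = 0.372 with an estimated correlation), with 8 of 14 higher, MAF, IL21, CXCL13 (0.77 ± 0.12) and CD200 (0.42 ± 0.08) among them, and 2 lower. Its call was lost without the 3 libraries rich in unnamed IDs (0.0582).

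Naive T cell genes were higher in 7 of 21 and lower in 3, with the transcription factors TCF7 (log2 0.68 ± 0.08) and SATB1 (0.69 ± 0.09), the kinase TXK (1.20 ± 0.11) and the homing receptor CCR7 (0.57 ± 0.08) higher. Of 22 activation genes 4 rose, such as CD38 (1.45 ± 0.19), and 8 fell, such as CD44 (-0.59 ± 0.07) and the amino acid transporter chain SLC3A2 (-0.72 ± 0.09). Of 12 inhibitory receptor genes 6 rose, among them LAIR1 (1.88 ± 0.20), CD274, which encodes PD-L1 (0.76 ± 0.10), and HAVCR2 (0.41 ± 0.08), and 2 fell, with LAG3 at -0.67 ± 0.08; CD44 did not pass without a composition factor (edgeR adjusted p = 0.0618). Among 17 chemokine receptors and homing molecules 8 rose, ITGA4 (0.83 ± 0.11) among them, and 2 fell. Among 25 cytokines 7 rose and 6 fell, with TNFSF13B, which encodes BAFF, at 2.44 ± 0.25 and IL24 at -1.13 ± 0.11; the list's median was -0.07 and its mean 0.10. Of 6 chemokines 3 rose and CCL20 fell; CCL17 rose by 1.36 ± 0.32, and CXCL10 had 0 counts in 3 of 4 control libraries and 19 to 40 in conditioned libraries. None of these 6 lists was called (camera adjusted p between 0.067 and 0.725), although the receptor, cytokine and chemokine lists passed after the length and GC correction (0.0222, 0.0341 and 0.0341) and the inhibitory and receptor lists passed with no filter (0.0217 and 0.0318).

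Interferon-stimulated genes rose together. OAS3, an antiviral RNA sensor, rose from 3.58 ± 1.16 to 27.8 ± 3.69 CPM (log2 2.95 ± 0.18, edgeR adjusted p = 8.22e-08, n = 4 per group), and MX1 by 2.45 ± 0.15 (8.22e-08). SAMD9L, an antiviral factor, rose from 1.99 ± 0.585 to 21.2 ± 7.04 CPM, a log2 fold change of 3.46 ± 0.24. OAS1 (2.07 ± 0.13) and DTX3L (1.78 ± 0.11) rose as well. Of the 35 type I interferon response genes 30 rose, 2 fell and 3 did not pass (median 1.01; camera adjusted p = 9.52e-21; adjusted p = 0.281 with an estimated correlation). The 2 that fell, named after their values were seen, were ISG15 (-0.88 ± 0.09) and ISG20 (-0.62 ± 0.09). In the list of genes induced by interferon gamma 8 of 17 rose and 1 fell (median 0.12; camera adjusted p = 0.00765; adjusted p = 0.301 with an estimated correlation). GBP4 (1.39 ± 0.12), GBP1 (1.13 ± 0.11) and GBP5 (0.80 ± 0.09), which encode guanylate-binding proteins, and CIITA, the regulator of MHC class II genes (1.73 ± 0.20), were among those higher.

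**Figure D2:**
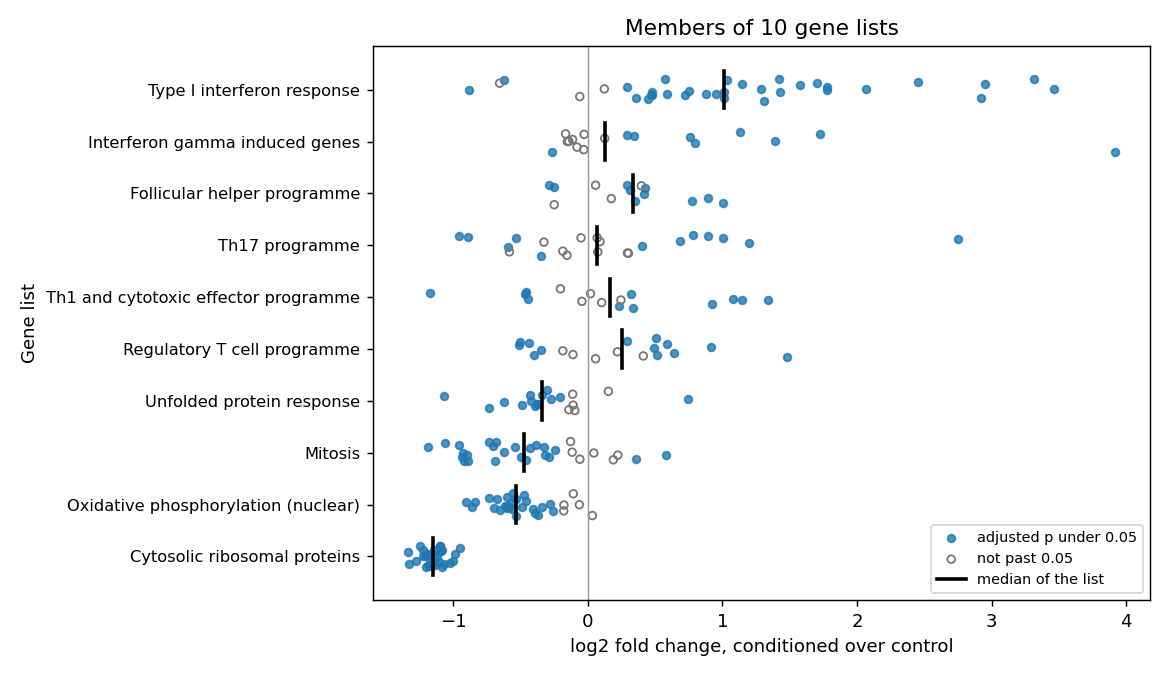
Log2 fold change, conditioned over control, of each measured member of 10 gene lists; filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. Interferon response genes lie mostly to the right with a median of 1.01, and the 32 ribosomal protein genes lie around -1.15.

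Ribosomal protein mRNAs were lower as a block. RPL32 had a log2 fold change of -1.22 ± 0.11 (edgeR adjusted p = 8.92e-07), RPL30 of -1.23 ± 0.11 and RPS16 of -1.18 ± 0.10. All 32 fell (camera adjusted p = 2.82e-42; adjusted p = 0.281 with an estimated correlation). Of 31 nuclear genes of oxidative phosphorylation 26 fell and none rose, with COX4I1 at -0.90 ± 0.09 and UQCRB at -0.84 ± 0.08 (median -0.53; camera adjusted p = 8.24e-10; adjusted p = 0.301 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 8 fell, such as MT-ND4 (-0.95 ± 0.21), beside the lower mitochondrial share of counts (camera adjusted p = 0.029; adjusted p = 0.615 with an estimated correlation). That list lost its call without conditioned library 1 (0.0519) or 2 (0.055) and after the length and GC correction (0.905).

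Fold changes followed transcript length. Across 12042 protein-coding genes, which are not independent replicates, the log2 fold change rose with the length of the longest transcript (Spearman rho = 0.42) and fell weakly with GC content (rho = -0.18). The tenth of genes with the shortest transcripts, with a median of 1250 bases, had a median log2 fold change of -0.38, and the tenth with the longest, 9445 bases, had 0.33. With each gene centred on its mean over the 8 libraries, so that only the difference between groups is informative, the slope of log2 CPM on log2 length was -0.12 ± 0.01 per doubling in control and 0.12 ± 0.07 in conditioned libraries (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest possible). Within groups, libraries further along the first principal component mostly had higher slopes. Control libraries ran from library 2 (-31.5, slope -0.13) to library 4 (-24.2, slope -0.11). Conditioned libraries 3 (39.0, slope 0.22) and 4 (28.2, slope 0.12) lay beyond 1 (20.4, slope 0.08) and 2 (20.6, slope 0.04). That component therefore does not separate the medium from the length trend. The ribosomal protein and respiratory chain mRNAs are short. A correction for length and GC, chosen after seeing the data, left their medians at -0.90 and -0.30.

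**Figure D3:**
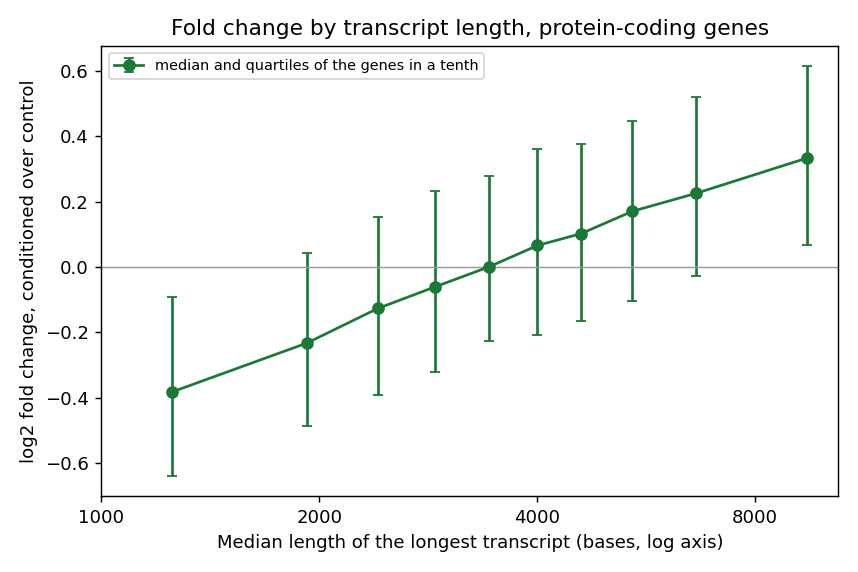
Log2 fold change, conditioned over control, of protein-coding genes in 10 groups by the length of their longest transcript in bases (log axis); points are medians and bars the quartiles over genes. The median rises from -0.38 in the shortest group to 0.33 in the longest.

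Genes of mitosis fell. CDC20, an activator of the anaphase-promoting complex, fell from 214 ± 15.7 to 93.9 ± 17.5 CPM (log2 -1.19 ± 0.11, edgeR adjusted p = 1.54e-06), and NEK2 (-1.06 ± 0.11), CCNB2 (-0.93 ± 0.10) and BIRC5 (-0.92 ± 0.11) fell too. Of 30 mitosis genes 22 fell, and KIF11 (0.36) and ASPM (0.58), named after their values were seen, rose (median -0.48; camera adjusted p = 9.34e-07; adjusted p = 0.312 with an estimated correlation). Genes of the G1 to S transition and DNA replication were split, with 7 of 29 higher, such as the helicase subunit MCM4 (0.72 ± 0.08), and 5 lower, such as CDT1 (-0.89 ± 0.14), RRM1 (-0.49 ± 0.09) and RRM2 (-0.57 ± 0.11) (camera adjusted p = 0.936). The mean log2 CPM of this list also divided the conditioned libraries. It was 5.84 and 5.88 in conditioned libraries 1 and 2 and 5.57 and 5.66 in 3 and 4. Control libraries lay between these pairs, at 5.68 to 5.82. RRM1 and RRM2 did not pass without a composition factor (edgeR adjusted p = 0.256 and 0.107). Of 13 replication-dependent histone genes 4 fell, with H2BC11 at -1.30 ± 0.12, and the list was not called (camera adjusted p = 0.0522). It passed without control library 2 (0.0252) or 4 (0.0452) or conditioned library 2 (0.0381), with upper-quartile (0.0497) or no composition factors (0.0189), and with no filter (0.00389) or the stricter filter (0.0466).

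Stress response lists differed in how many of their genes fell. HSPA5, which encodes the endoplasmic reticulum chaperone BiP, fell by 1.07 ± 0.08 on the log2 scale (edgeR adjusted p = 2.21e-07). In the unfolded protein response 13 of 19 fell and EDEM1 rose (0.74 ± 0.09) (camera adjusted p = 0.00222; adjusted p = 0.281 with an estimated correlation), and in the heat shock response 8 of 14 fell, with HSPA8 at -0.75 ± 0.09, and 1 rose (0.0245; adjusted p = 0.281 with an estimated correlation). In the amino acid response 12 of 28 fell, with DDIT3 at -1.07 ± 0.11 and ATF4 itself at -0.79 ± 0.09, and 3 rose, with ALDH1L2 at 0.90 ± 0.09 (0.0393; adjusted p = 0.592 with an estimated correlation). Of 16 immediate early genes, a list fixed as a sign of RNA quality, 10 fell, with ATF3 at -0.97 ± 0.08. In that list 2 rose (camera adjusted p = 0.00275, and 0.281 with an estimated correlation). Metallothionein and zinc response genes fell in 5 of 8, with MT2A at -0.82 ± 0.09 (0.00736; adjusted p = 0.281 with an estimated correlation), and in the oxidative stress list 7 of 16 fell, with the ferritin chains FTL (-0.88 ± 0.10) and FTH1 (-0.81 ± 0.10), and 3 rose (0.0588, not called). Of 19 p53 targets 7 rose and 5 fell, with GADD45A at -1.02 ± 0.07; the median was 0.12 while camera pointed down (0.802). Calls were lost without a composition factor for the unfolded protein (0.0506), heat shock (0.143) and amino acid (0.151) lists, after the length and GC correction for heat shock (0.0845) and metallothioneins (0.0879), and without the 3 libraries rich in unnamed IDs for heat shock (0.0522). The amino acid list also lost its call without control library 2 (0.0623) or conditioned library 3 (0.069) or 4 (0.0519) and with the stricter filter (0.0501), and the oxidative stress list passed without control library 2 (0.0464) and with no filter (0.005).

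Metabolic lists held changed genes and genes that did not pass. For glycolysis the mean log2 CPM of the list divided the conditioned libraries. Libraries 1 and 2 (both 8.65) lay within the control range of 8.64 to 8.72, and 3 and 4 (8.25 and 8.31) lay below it. GAPDH (log2 -1.11 ± 0.14), ALDOA (-0.82 ± 0.12) and 8 other glycolysis genes of 23 fell and 1 rose (camera adjusted p = 0.0481; adjusted p = 0.698 with an estimated correlation). That call was lost without control library 3 (0.0559) or 4 (0.0715), conditioned library 3 (0.112) or 4 (0.132) or the 3 libraries rich in unnamed IDs (0.0807), with upper-quartile (0.0544) or no composition factors (0.143), with the stricter filter (0.0609) and with library weights (0.0525). Of 23 hypoxia genes 12 fell and none rose, among them MXI1 (-0.66 ± 0.07) and the collagen prolyl hydroxylase chain P4HA2 (-0.83 ± 0.14) (camera adjusted p = 0.0101; adjusted p = 0.499 with an estimated correlation). Of 11 fatty acid genes 4 rose, FADS2 (0.94 ± 0.09), SREBF1 (0.77 ± 0.09), ELOVL6 (0.86 ± 0.13) and FASN (0.37 ± 0.09) (0.029; adjusted p = 0.281 with an estimated correlation), a call lost after the length and GC correction (0.0683), as was that of FASN (0.443), and without the 3 libraries rich in unnamed IDs (0.0522). In cholesterol biosynthesis 3 of 24 rose, INSIG1 (0.60 ± 0.08) among them, and 9 fell, and of 8 LXR targets 3 rose and 1 fell; neither list was called (camera adjusted p = 0.616 and 0.462).

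Signalling responses were mixed. Targets of glucocorticoids fell in 7 of 19 and rose in 3, with TSC22D3 (GILZ, -1.10 ± 0.08), SGK1 (-0.93 ± 0.08) and DUSP1 (-1.03 ± 0.09) lower (camera adjusted p = 0.029; adjusted p = 0.281 with an estimated correlation). Retinoic acid and vitamin D response genes rose in 6 of 12 and fell in 1, with the transglutaminase TGM2 at 2.65 ± 0.20 and VDR at 0.64 ± 0.07 (0.0245; adjusted p = 0.281 with an estimated correlation). Of 19 transforming growth factor beta response genes 9 rose and 2 fell, with TGFBI at 1.63 ± 0.17, the receptor TGFBR2 at 0.75 ± 0.09 and ID3 at -1.19 ± 0.13 (0.114, not called). Of 18 cyclic AMP and prostaglandin response genes 6 rose, with PDE3B at 1.36 ± 0.14, and 10 fell, with the prostaglandin receptor PTGER4 at -0.56 ± 0.08 (0.0549, not called); PTGER4 did not pass without a composition factor (0.0892), nor did CYP1A1 (0.199). Aryl hydrocarbon receptor response genes were split, 3 of 7 higher and 2 lower, with AHR itself higher, AHRR at 0.52 ± 0.09 and CYP1A1 at -0.54 ± 0.10 (0.354). STAT3 targets (4 of 17 higher, 3 lower, 0.905) and NF-kB targets (2 of 20 higher, 4 lower, 0.685) were not called. The glucocorticoid call was lost without a composition factor (0.152) and in limma-voom (0.0746), and the retinoic acid call in limma-voom (0.088). The cyclic AMP list passed without control library 2 (0.0464) or 3 (0.041) or conditioned library 3 (0.0323) or 4 (0.0462), without the 3 libraries rich in unnamed IDs (0.0452), after the length and GC correction (0.00909) and with no filter (0.00358).

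Markers of other cell types moved in both directions. COL6A3, a collagen chain in the decidual stromal list, rose from 34.7 ± 4.75 to 108 ± 13.2 CPM (log2 1.65 ± 0.11, edgeR adjusted p = 1.01e-07), and PDGFRB (0.77 ± 0.21) and ACTA2 (0.56 ± 0.16) rose, so that 3 of 7 measured members were higher (camera adjusted p = 0.029; adjusted p = 0.348 with an estimated correlation). DCN, LUM and IGFBP1 from that list had 0 counts in all 8 libraries and PRL had at most 1 count, all 4 named after their values were seen. The call was lost without control library 4 (0.0974), without conditioned library 1 (0.109), 3 (0.0708) or 4 (0.0519), with no composition factor (0.0902), no filter (0.0893) or limma-voom (0.0618). Of 8 monocyte and dendritic cell markers 3 rose, FCER1G (0.84 ± 0.17), S100A9 (0.86 ± 0.20) and VCAN (1.39 ± 0.40) (0.488), and of 5 B cell markers CD22 rose (0.92 ± 0.19) while CD79B (-0.66 ± 0.09) and CD19 (-0.87 ± 0.24) fell (0.526). Of 5 CD8 and gamma-delta T cell markers 1 rose and CD8A, named after its value was seen, fell (-0.72; camera adjusted p for the list 0.73). Among NK cell markers NKG7 (-0.53 ± 0.10) and NCR3 (-0.59 ± 0.17) fell and GNLY rose (0.32 ± 0.10, edgeR adjusted p = 0.0142), the last not without control library 2 (0.0623) or 4 (0.0576). Without a composition factor NKG7 and NCR3 did not pass (edgeR adjusted p = 0.233 for both), nor did CD19 (log2 -0.54, 0.0626). After the length and GC correction NKG7 and NCR3 did not pass either (0.786 and 0.496). Without the 3 libraries rich in unnamed IDs NCR3 (-0.43, 0.185) and CD19 (-0.79, 0.0579) did not pass, with fewer libraries tested. KRT18, named after its value was seen, was the 1 of 4 epithelial and endothelial markers that fell (-0.65), and the single measured platelet and erythroid marker, ITGA2B, also named after its value was seen, did not pass (-0.59, edgeR adjusted p = 0.157).

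Interferon-stimulated genes were among the largest rises. SAMD9L, SAMD9 (3.01 ± 0.24), OAS3, IFI44L (2.92 ± 0.27), MX1 and EIF2AK2, which encodes the double-stranded RNA kinase PKR (2.46 ± 0.19), were 6 of the 12, and TGM2, ITPRIPL2 (2.62 ± 0.22), the transcription factor SIM1 (2.59 ± 0.30), THSD7B (2.50 ± 0.26), TNFSF13B and the secreted ligand WNT5B (2.38 ± 0.15) were the rest. The largest fall was that of STMN4, from 9.77 ± 1.05 to 2.22 ± 0.313 CPM (log2 -2.12 ± 0.15, edgeR adjusted p = 1.45e-07). The stress-induced GADD45B (-1.78 ± 0.10) and GADD45G (-1.67 ± 0.25), GCNA (-1.77 ± 0.08), the Notch target HES1 (-1.74 ± 0.18), TNFAIP8L3 (-1.70 ± 0.18) and GPRC5C (-1.65 ± 0.17) were also among the 12. The snoRNA host transcripts SNHG19 (-1.64 ± 0.18) and SNHG1 (-1.60 ± 0.09) belonged to them too, as did RN7SL471P (-1.79 ± 0.35), RPL9P7 (-1.61 ± 0.24) and RPL18AP3 (-1.54 ± 0.24), pseudogene-like IDs whose counts are uncertain because they share sequence with abundant RNAs. SNHG1 had also been placed in the fixed list of nuclear-retained RNAs, and it had the largest fall of that list's changed members. In the list 3 of 5 fell, with MALAT1 at -0.98 ± 0.19 and NEAT1 at -0.71 ± 0.16 (camera adjusted p = 0.00359, and 0.313 with an estimated correlation).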

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

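The tests below were set before their results were seen, except the count over other splits of the libraries and the length and GC correction. Across 458 checks of 4 libraries each, 21 single libraries lay apart from the other 3 of their group, about the 1 in 20 that chance gives. Such a check cannot see a group that divides into pairs. On the second principal component conditioned libraries 1 and 2 (-13.8 and -19.9) lay apart from 3 and 4 (17.3 and 8.75). Conditioned library 3 had the lowest CD44 (8.58 log2 CPM), NEK2 (5.35) and ATF4 (8.16) and the highest ITGA4 (4.32) and HSPA1B (4.91). Conditioned library 4 had the lowest CIITA (1.62) and the highest XBP1 (7.18), and conditioned library 2 the highest FCER1G (2.42). Control library 2 had the highest NEK2 (6.98), FDFT1 (8.73) and HSPA8 (11.89), and control library 3 the lowest MT-ND2 (10.15). Control library 4 had the lowest GADD45A (7.94) and the highest CXCL10 (-0.49), the single control library with a CXCL10 count. Among list means, control library 2 was lowest for genes induced by interferon gamma (5.53), control library 1 was lowest for glycolysis (8.64) and control library 4 was highest for monocyte and dendritic cell markers (1.58). Conditioned library 1 had 32060000 counts against at most 21688000 in the other 3. Conditioned library 4 gave 21.0% of its counts to 2 unnamed gene IDs, 38.1% to its 100 most abundant genes and 75.7% to protein-coding genes.

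The groups differed by more than a random division of the libraries gives. Of the 35 ways to split the 8 libraries into 4 and 4, 1 gave as many as 6863 genes in edgeR, the real one. The highest other split gave 0. Every other split mixes both groups, so the group difference widens the spread and pushes its count towards 0. The count restates the group difference and cannot tell the medium from preparation or time. At an unadjusted p under 0.05 the real split gave 7692 genes and the others between 31 and 1748, and no other tool was run on the splits.

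The first pattern is the lower ribosomal protein mRNAs. A trend with transcript length or GC content is argued against as the whole cause, since the list's median was -0.90 after the correction, against -1.15 before, and 32 of 32 genes stayed lower. The scaling between libraries is argued against as well, since the median nearest to 0 over the scalings was -0.82, without a composition factor. A lower level of these mRNAs in cells given conditioned medium may be biological, as a hypothesis found and tested on the same data. Part of the size is shared with the length trend, whose origin stays open. The list was fixed as a sign of RNA quality, and the other lists of that kind pointed down too. Their camera adjusted p were 0.00275 (immediate early genes), 0.00359 (nuclear-retained RNAs), 0.029 (mitochondrially encoded mRNAs) and 0.0522 (replication-dependent histones, not called). The nuclear-retained list holds the snoRNA host transcript SNHG1, which had the largest fall of its changed members. RNA quality or preparation that differed between the groups was not tested as a cause of the fall.

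The second pattern is the higher interferon response genes. The length and GC trend is argued against as the cause, since the median was 0.98 after the correction, against 1.01 before, with 30 genes still higher. No single library carried it, since the lowest median with any 1 library left out was 0.93. A response to interferon, or to another inducer of these genes in the conditioned medium, is a candidate explanation that no label allows to be separated from any other difference between the cultures, such as time; ISG15 and ISG20, named after their values were seen, were lower and go against a uniform rise of the list.

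The third pattern is that longer transcripts were higher. Short abundant genes alone are argued against, since rho was 0.40 across genes of at least 1000 bases without ribosomal protein and respiratory chain genes. GC content is argued against with rho 0.39 after its removal, and a difference in depth with rho 0.43 after every library was thinned to the smallest total. RNA integrity or library preparation that differed with the group cannot be told apart from an effect of the medium. The slopes on length separate the groups (exact permutation p = 0.0286), and no label gives preparation batches. The share of counts in ribosomal RNA genes, mitochondrially encoded ones included, separates the groups too and was not tested. It was 2.31% to 3.27% in control and 0.996% to 1.68% in conditioned libraries. The mitochondrial share of counts given above also holds the mitochondrially encoded ribosomal RNA. These shares overlap and are not separate signs of a difference in preparation. Any single gene with a modest fold change may carry part of the length trend. After the correction 5259 of the 6863 calls were still made in the same direction.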

How the results depend on the processing

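The length and GC correction and both settings on the unnamed gene IDs were chosen after seeing the data. With DESeq2 size factors, upper-quartile factors, DESeq2, both limma-voom fits, no filter and the stricter filter, between 6594 and 6902 genes changed, against 6863. Leaving out each library in turn gave between 5930 and 6869. The length and GC correction gave 6929, of which 5276 were shared with the 6863, 5259 in the same direction and 17 in the opposite one, and removal of the 2 unnamed IDs gave 6854. Without a composition factor 6549 genes were higher and 1028 lower, with 4479 calls shared; that setting puts the median of all genes at 0.34. Without the 3 libraries rich in unnamed IDs 4140 genes changed (2086 higher, 2054 lower), of which 3961 were shared; fewer libraries were tested.

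Same-numbered libraries deviated from their group means with correlations between -0.15 and -0.04, and 0 of 4 control libraries correlated best with its own number. These values gave no sign that the numbers pair the libraries. They cannot exclude a shared donor or day, since all other differences between libraries of a group enter the same correlations. A fit with the replicate number as a block gave 6298 genes, 6237 of them shared, and kept all 175 named genes and all 43 lists on their side of the threshold.

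Among 175 tested named genes, 175 kept their direction and side with DESeq2, DESeq2 size factors, upper-quartile factors and limma-voom. Under no composition factor 27 lost and 2 gained a call, and PIM1 turned to 0.0243 from -0.31. Under the length and GC correction 11 lost and 1 gained, and BATF turned to 0.0914, MT-ND4L to 0.0416 and H2BC12 to 0.124; the cause was not tested. Without the 3 libraries 11 lost their call and 0 turned, with fewer libraries tested. Some of the 11 kept their fold, such as FOS (-0.67 against -0.65 with all libraries). Others had a smaller one, such as NCR3 (-0.43 against -0.59).

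Of the 43 lists, 19 were called by camera, 34 by fry and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. The interferon and ribosomal protein lists each had an adjusted p of 0.281 there, and the Th17 list one of 0.0169 with fry. Without a composition factor the medians of the hypoxia (0.10), amino acid (0.10), glucocorticoid (0.18), glycolysis (0.13) and heat shock (0.01) lists turned positive, each below the median of all genes. Low levels limit the test of IL17A, IL22, CCR6 and IL10, which fell below the filter. Their mean levels lay between 0.09 (CCR6) and 0.90 CPM (IL22) in control libraries. In conditioned libraries they lay between 0.15 (IL17A) and 0.37 CPM (IL22). Library totals were between 15952803 and 32506815 counts.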

Other observations

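Genes of interferons and their receptors were looked at after the interferon response genes had been seen. All 13 listed interferon alpha genes had 0 counts in the 8 libraries, so none was detected. This cannot tell absence from reads lost in counting. IFNB1 had 1 to 27 counts in control and 11 to 22 in conditioned libraries (log2 0.30, edgeR adjusted p = 0.592). The interferon lambda genes IFNL1 (log2 -0.68, edgeR adjusted p = 0.0348) and IFNL3 (-0.51, 0.0147) fell and IFNL2 did not pass (-0.35, 0.131), with reads that may be split between near-identical copies. The type I receptor chains IFNAR1 (0.71, 0.000311) and IFNAR2 (0.55, 0.000218) rose, and the lambda receptor chain IFNLR1 (-0.59, 0.000141) and its partner IL10RB (-0.50, 0.000508) fell. IFNGR2 fell (-0.24, 0.0221) and IFNGR1 had a log2 fold change of -0.07 (0.518).

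Ribosomal protein mRNAs belong to a class that starts with a 5' terminal oligopyrimidine motif, through which growth signalling controls their translation and stability. The hypothesis that the whole class was lower was tested, before its values were seen, on 22 other genes listed for this motif. Most of them are translation genes. The median log2 fold change of the 22 was -0.82, below the 5th percentile (-0.30) of 10000 random lists matched on expression and length, and 20 fell. VIM (-0.04, edgeR adjusted p = 0.73) and EEF1G (-0.63, 0.0566), named after their values were seen, did not pass. EEF1G had 1.89 CPM in control libraries, so low counts limit its test. From the same list EEF1B2 had 812 and EEF1D 518 CPM there, both also named after their values were seen. After the length and GC correction the median was -0.69 and without a composition factor -0.49.

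Some transcripts that host small nucleolar RNAs carry the same motif. The prediction was written after SNHG1, SNHG19 and SNHG32 had been seen, which were left out, and before the others were. All 13 listed host genes fell, with a median of -1.20 against a 5th percentile of -0.44 for matched random lists, -0.93 after the length and GC correction and -0.88 without a composition factor. Both results are consistent with a lower level of the class of transcripts with this motif, and the 2 lists were not corrected for shared regulation between their genes.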
